A study of Homo sapiens with 3 samples.

How the data were processed

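RBPJ, L3MBTL3 and input DNA from MDA-MB-231 cells were sequenced, 1 library each, and peak lists of the RBPJ and L3MBTL3 libraries were analysed. Per the labels' protocols, sonicated chromatin was precipitated with an antibody, libraries were sequenced with 50 cycles from one end on an Illumina HiSeq instrument to 30 to 40 M aligned reads (M, megareads) per sample, and reads were adaptor-trimmed with Trimmomatic and aligned to hg19 with BWA 0.7.15. Peaks were called with MACS2, per the submitters' processing notes. Its version and cutoff, and whether the input was its control, are not given in the sources used here. Each list belongs to 1 library, so no replicates were pooled in it.

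The deposited columns used were the peak's start and end, its summit, the fold enrichment at the summit (a ratio over the caller's local background), the -log10 p and the -log10 q. The deposited score column equals 10 times the -log10 q truncated to a whole number for every peak. The smallest -log10 q was 1.31 in the RBPJ and 1.30 in the L3MBTL3 list, so the largest q was 0.0487 and 0.0498. All peaks were on chromosomes 1 to 22 and X, so using assembled chromosomes only, an alternative set beforehand, changes nothing. Smallest widths were 55 bp (209 RBPJ peaks) and 50 bp (28 L3MBTL3 peaks). Since peaks give no read counts, the error of a single fold is unknown, and the shorter L3MBTL3 list cannot be read as less binding.

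Coordinates are 1-based in hg19, and sequence and genes come from GRCh37 and GENCODE 44 lifted to that build (19748 protein-coding genes, 78394 TSS). A peak was shared if it overlapped a peak of the other list by at least 1 bp. The count was compared with 1000 random placements of the L3MBTL3 peaks outside assembly gaps on the same chromosome, and with 1000 placements at the same signed distance from a random protein-coding TSS. A TSS was CpG-rich where the observed over expected CpG ratio in 1 kb was above 0.6 (56.4% of TSS). Strength was compared by medians against 10000 random lists and by the percent of peak pairs in which the shared peak was higher, with 1000 bootstrap resamples. Alternatives of the strength comparison were set beside each other by that percent, which, like the tests between peak classes, was not part of the plan fixed beforehand. A promoter was within 1 kb of a TSS.

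Motif words on either strand were sought within 100 bp of summits and in windows centred 2 kb up- and downstream. The RBPJ words were YGTGGGAA (Y is C or T) and TGGGAA, and 13 words of other factors were fixed with them: AP-1 TGASTCA, ETS ACCGGAAGT, RUNX TGTGGTT, TEAD GGAATG, NFY RRCCAATSR, CRE TGACGTCA, NRF1 GCGCATGCGC, YY1 AAGATGGCGGC, CTCF CCASYAGRKGGC, ZNF143 ACTACAATTCC, E-box CACGTG, NF-kB GGGRNNYYCC and GC box GGGGCGGGG. Fisher's exact tests were two-sided, with Benjamini-Hochberg adjustment over 10 tests of RBPJ words, 65 of other words, 45 between classes and 30 between promoter and other peaks. Odds ratio intervals are 95% Woolf intervals, with 0.5 added to each count where one was 0. Shares have 95% Wilson intervals, which cover counting error only. Neighbouring peaks and genes are not independent, so p values may be too small.

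Gene lists were fixed before the data were examined: Notch targets, Notch pathway components, RBPJ corepressors and demethylase complexes, AP-1 and immediate early genes, YAP/TEAD targets, mesenchymal, luminal epithelial, NF-kB targets, p53 targets, ribosomal proteins, replication-dependent histones, cell cycle, HOX and olfactory receptor genes. SHARPIN was listed by symbol and is not an RBPJ corepressor, so the corepressor list was also tested without it, a choice made after seeing the data. A gene counted as near when a summit was within 10 kb of any of its protein-coding TSS, with adjustment over the 14 lists for each peak set. An odds ratio of a list with 0 members near is given as 0. Named peaks, by a rule fixed at the same time, are the 15 shared, 10 RBPJ-only and 10 L3MBTL3-only peaks with the highest fold, members of the first 3 lists with a summit within 10 kb (some are not reported here), and from other lists the members with the highest fold.

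Alternatives fixed before the data were examined were a -log10 q of at least 5 (in both lists for the overlap, and of the RBPJ peak only for shared peaks elsewhere), folds of at least the list median, other overlap rules, local placement within 100 kb, TSS of the same CpG class, other promoter windows, motif windows and controls, gene distances of 1 and 50 kb, and each chromosome left out in turn. Chosen after seeing the data were shared peaks near gene lists with that q in both lists, peaks merged into regions, removal of repeated sequence, TSS on the same chromosome, motif controls of the same CpG class, and gene lists compared within chromosomes by a Mantel-Haenszel odds ratio with an exact p, which replaced a chi-square approximation after the latter's results had been seen. Sequence counted as repeated where the median of 5 windows of 50 bases per peak occurred more than once in the genome (95 RBPJ and 16 L3MBTL3 peaks). Correlations used 100000 permutations. The overlap code was tested on simulated data, in which it found 100 of 100 shared peaks planted in a list of 444, and its count on the real lists equalled that of bedtools 2.31.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9 were used. The input library was not analysed here.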

Results

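Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in MDA-MB-231, a mesenchymal-like, hormone receptor-negative human breast cancer cell line. One antibody was against RBPJ (also called CBF1 or CSL), the DNA-binding transcription factor of the Notch pathway, and the other was against L3MBTL3, a methyl-lysine reader of the MBT protein family. Each antibody had 1 library, and the input DNA library was not analysed here. With 1 library per antibody there is no replicate error: intervals and tests below are over the peaks or genes of these libraries, and describe them rather than repeated experiments. The labels give 30 to 40 M aligned reads (M, megareads) for each library. The RBPJ list held 2926 peaks with a median width of 94 bp and a median fold enrichment of 5.08 (range 2.09 to 21.3). The L3MBTL3 list held 444 peaks with a median width of 86 bp and a median fold enrichment of 5.57 (range 2.87 to 14.5). Fold enrichments and q values are those deposited with the peaks, and they were compared only within a list. Read counts behind single peaks are unknown.

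The first question, stated by the series, was where the 2 proteins lie together on chromatin. RBPJ and L3MBTL3 peaks overlapped at the promoters of HES4 and HEY2, which encode transcriptional repressors induced by Notch, of NOTCH1, which encodes a Notch receptor, and of the RBPJ gene itself. In all, 127 of 444 L3MBTL3 peaks (28.6%, 95% Wilson interval 24.6 to 33.0) overlapped 128 of 2926 RBPJ peaks (4.37%, 3.69 to 5.18). When the L3MBTL3 peaks were placed at random on their own chromosomes 1000 times, a mean of 0.156 and at most 2 overlapped an RBPJ peak. When each was moved to the same distance from a random transcription start site (TSS), a mean of 6.61 and at most 16 did, so the observed count was 19.2 times that mean (16.5 to 22.2 from the Wilson interval). With TSS drawn from the same CpG class the mean was 11.4, the highest count was 24, and the observed count was 11.1 times the mean. Neither TSS draw was matched on gene activity, so these ratios do not take out a common preference for active promoters. Counting peaks within 1 kb of each other as shared raised the share to 49.3% (44.7 to 54.0). That rule was compared only with random placement on the same chromosome (mean 1.07) and not with placement at random TSS. How much of the 49.3% a common preference for promoters gives was therefore not tested.

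**Figure D1:**
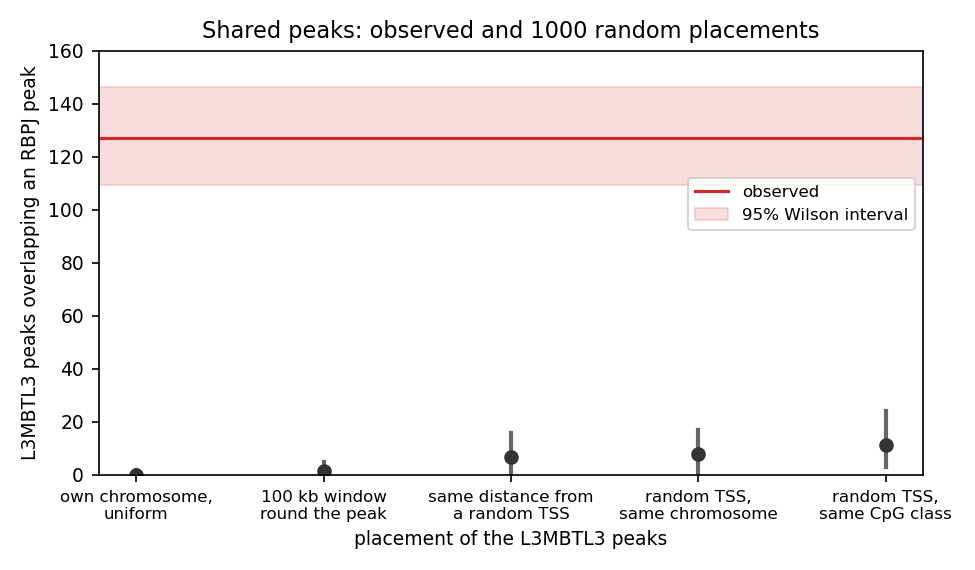
Number of L3MBTL3 peaks that overlap an RBPJ peak (y axis) against 5 ways of placing the L3MBTL3 peaks at random (x axis). Points are means and bars the lowest to highest count of 1000 placements, and the red line and band are the observed 127 peaks with their 95% Wilson interval, which lies above all placements.

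The shared RBPJ peak with the highest RBPJ fold enrichment lay in the UTR of HES4, 20 bp from a TSS (chromosome 1, 935342 to 935715, hg19), with a fold of 15.6 for RBPJ and 6.67 for L3MBTL3 and summits 37 bp apart. It held 1 high-affinity RBPJ site, TGTGGGAA on the minus strand at 935548 to 935555. At HEY2 (chromosome 6, 126070359 to 126070947, in an intron 78 bp from a TSS) the folds were 8.86 for RBPJ and 11.7 for L3MBTL3, over 2 copies of CGTGGGAA at 126070565 to 126070572 and 126070773 to 126070780. Another shared peak lay 13.9 kb upstream of NRARP, a Notch-induced feedback inhibitor, inside an intron of EXD3 (chromosome 9, 140210487 to 140210805; RBPJ fold 9.74, L3MBTL3 fold 8.01). One lay 64.9 kb upstream of HES1, the most widely used Notch target gene, between genes (chromosome 3, 193788824 to 193789253; 8.07 and 6.56). One lay 10.6 kb upstream of NODAL, a TGF-beta family ligand (chromosome 10, 72218110 to 72218439; 8.88 and 4.92). The peak of the whole L3MBTL3 list with the highest fold, 14.5, was shared and had its summit 166 bp from a TSS of SIPA1L2 (chromosome 1, 232765546 to 232766344). The RBPJ peak it overlapped (232765821 to 232766108, fold 10.3) held no high-affinity site in it or within 100 bp. The remaining 9 of the 15 shared peaks with the highest RBPJ fold were all within 1 kb of a TSS: those of MID2, CCDC102B, NAPG, UBE2D4, ZBTB18, SLC12A2, FLOT1, TPPP and TADA2B, with RBPJ folds of 7.83 to 10.8. At the promoter of RBPJ itself (chromosome 4, 26321061 to 26321471, UTR) the folds were 7.57 for RBPJ and 12.3 for L3MBTL3, over CGTGGGAA at 26321253 to 26321260.

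**Figure D2:**
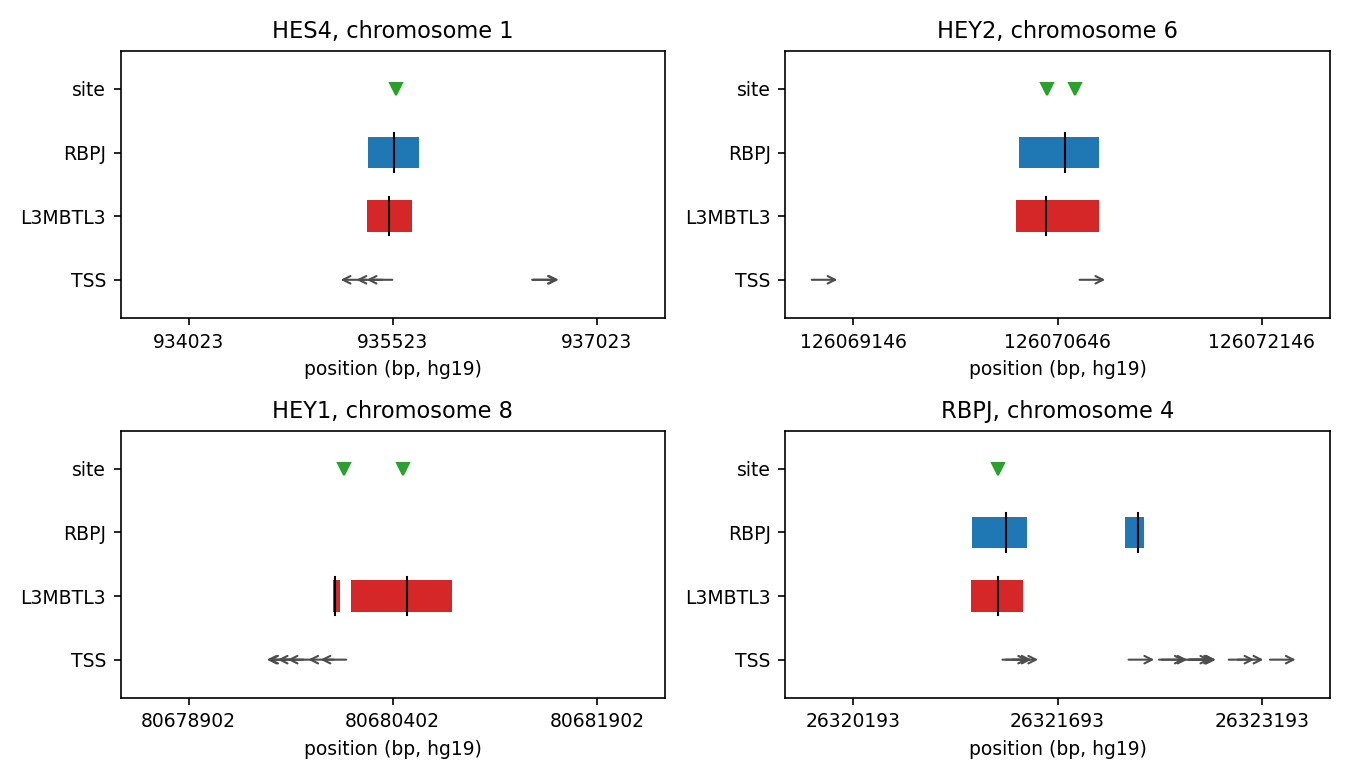
Peaks of both lists in 4 kb around HES4, HEY2, HEY1 and RBPJ, with position in bp (hg19) on the x axis. Boxes are RBPJ (blue) and L3MBTL3 (red) peaks with their summits as black lines, green triangles are high-affinity RBPJ sites in or within 100 bp of a peak, and arrows are protein-coding TSS with their direction. The HEY1 window holds L3MBTL3 peaks, 2 sites (1 inside the larger peak and 1 between the peaks) and no RBPJ peak.

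Several of the strongest peaks were in 1 list only. The RBPJ-only peak with the highest fold, 21.3, lay in an intron of ZNF675 on chromosome 19 (23709146 to 23709682), 131 kb from the nearest TSS, that of ZNF91, and held CGTGGGAA. Of the 10 strongest RBPJ-only peaks, only that of TAGLN2, an actin-binding protein (chromosome 1, 159894274 to 159894814, fold 12.4), was within 1 kb of a TSS. The others lay nearest to NR4A2, SEPTIN10 (in an SH3RF3 intron), ECE1, UBE2E3, ANKRD33B, ARHGAP26, PTPRE and AZIN2, 9.48 to 448 kb from the TSS, with folds of 10.8 to 15.02. The strongest L3MBTL3-only peak lay 416 bp upstream of HEY1, a further Notch-induced repressor (chromosome 8, 80680095 to 80680838, fold 11.3), with 2 high-affinity RBPJ sites in it or within 100 bp and the nearest RBPJ summit 15924 bp away. The next were near SKOR1 (14.6 kb from its TSS, fold 10.6), RASIP1 (coding exon, 0.198 kb from a TSS, 9.03), STARD8, TWIST2, ADCY7, SLC12A2, SFMBT1, MAP3K8 and NAPG, the last 7 with folds of 7.87 to 8.54. Those of RASIP1, SLC12A2, MAP3K8 and NAPG had an RBPJ summit 151 to 298 bp away, so they lie beside an RBPJ peak without touching one. Each of these promoters also held another L3MBTL3 peak that was shared.

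Within overlapping pairs, the summits of the 2 proteins were close. Over 133 pairs the median distance was 53 bp (quartiles 24 and 108 bp, 95% bootstrap interval of the median 42 to 66), and 98 pairs were within 100 bp. A random base of the RBPJ peak in place of its summit gave median distances of 48 to 80 bp (mean 61.2) in 1000 draws, so the observed median was not below that range.

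Shared peaks had higher fold enrichments than peaks found with 1 antibody. The median RBPJ fold was 5.57 (quartiles 4.86 and 6.35) in 128 shared peaks and 5.08 (4.52 and 5.75) in 2798 RBPJ-only peaks, above the medians of all 10000 random lists of 128 RBPJ peaks. A shared peak had the higher RBPJ fold in 63.0% of comparisons with an RBPJ-only peak (95% bootstrap interval 57.6 to 68.2). The median L3MBTL3 fold was 5.86 (5.02 and 6.78) in 127 shared and 5.43 (4.88 and 6.08) in 317 L3MBTL3-only peaks, at the 99.9 percentile of random lists. Shared L3MBTL3 peaks had the higher fold in 59.3% of comparisons (52.8 to 65.2). Away from promoters, 22 shared RBPJ peaks had the higher fold in 54.1% of comparisons (40.5 to 66.8) and 25 shared L3MBTL3 peaks in 63.6% (48.5 to 76.8), intervals that both include no difference.

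L3MBTL3 peaks lay at promoters more often than RBPJ peaks. Summits within 1 kb of a protein-coding TSS made up 82.7% of L3MBTL3 peaks (78.9 to 85.9) and 64.1% of RBPJ peaks (62.4 to 65.8), against 3.21% of random positions (Fisher's exact test between the lists, two-sided, odds ratio 2.67, 2.06 to 3.45, p = 7.18e-16). Of the promoter peaks, 99.5% (L3MBTL3) and 94.5% (RBPJ) were at CpG-rich TSS. Shared RBPJ peaks were at promoters in 82.8% of cases (75.3 to 88.4) and RBPJ-only peaks in 63.3% (61.5 to 65.03; odds ratio 2.80, 1.76 to 4.46, Fisher's exact p = 2.91e-06). Shared RBPJ peaks overlap L3MBTL3 peaks by definition, so this difference is not independent of that between the lists. For shared and L3MBTL3-only L3MBTL3 peaks the shares were 80.3% and 83.6% (odds ratio 0.801, 0.472 to 1.36, Fisher's exact p = 0.408). Introns outside promoters held 14.5% of RBPJ and 5.41% of L3MBTL3 summits, and intergenic sequence 20.4% and 10.8%.

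The high-affinity RBPJ recognition sequence was more frequent in shared peaks than in peaks of either list alone. The word YGTGGGAA lay within 100 bp of the summit in 20.3% of shared peaks (14.3 to 28.1), 7.97% of RBPJ-only peaks (7.02 to 9.03) and 6.94% of L3MBTL3-only peaks (4.63 to 10.3). Windows of shared and RBPJ-only peaks were centred on RBPJ summits, and those of L3MBTL3-only peaks on L3MBTL3 summits. Windows 2 kb to either side held it in 1.95%, 1.54% and 0.631% of cases. Each class exceeded its flanks, with odds ratios of 12.8 (4.78 to 34.2), 5.55 (4.31 to 7.15) and 11.7 (4.01 to 34.4) and Fisher's exact, Benjamini-Hochberg adjusted p of 3.46e-09, 6.37e-45 and 9.69e-08. The size depended on the controls and windows: over 6 alternatives the odds ratios were 13.8 to 44.4 for shared, 5.74 to 9.03 for RBPJ-only and 3.21 (random TSS as controls) to 45 (stricter q, where 0 of 112 controls held the word) for L3MBTL3-only peaks. Shared peaks exceeded RBPJ-only peaks (odds ratio 2.94, 1.87 to 4.62, adjusted p = 1.83e-04 over 45 Fisher's exact tests) and L3MBTL3-only peaks (3.42, 1.86 to 6.30, adjusted p = 8.76e-04). The core TGGGAA was in 34.4% of shared, 29.3% of RBPJ-only and 13.9% of L3MBTL3-only windows, against 17.2%, 16.8% and 18.6% of flanks, and did not differ detectably between shared and RBPJ-only peaks (Fisher's exact, adjusted p = 0.621). The core passed the Fisher's exact test against flanks in shared and RBPJ-only peaks (adjusted p = 3.45e-04 and 2.31e-38) and not in L3MBTL3-only peaks (odds ratio 0.705, 0.484 to 1.03, adjusted p = 0.0756), where 3 alternatives gave an odds ratio above 1. Over all 444 L3MBTL3 peaks the core did not pass either (19.8% against 17.8%, adjusted p = 0.370), although it did under 4 alternatives (Fisher's exact tests).

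**Figure D3:**
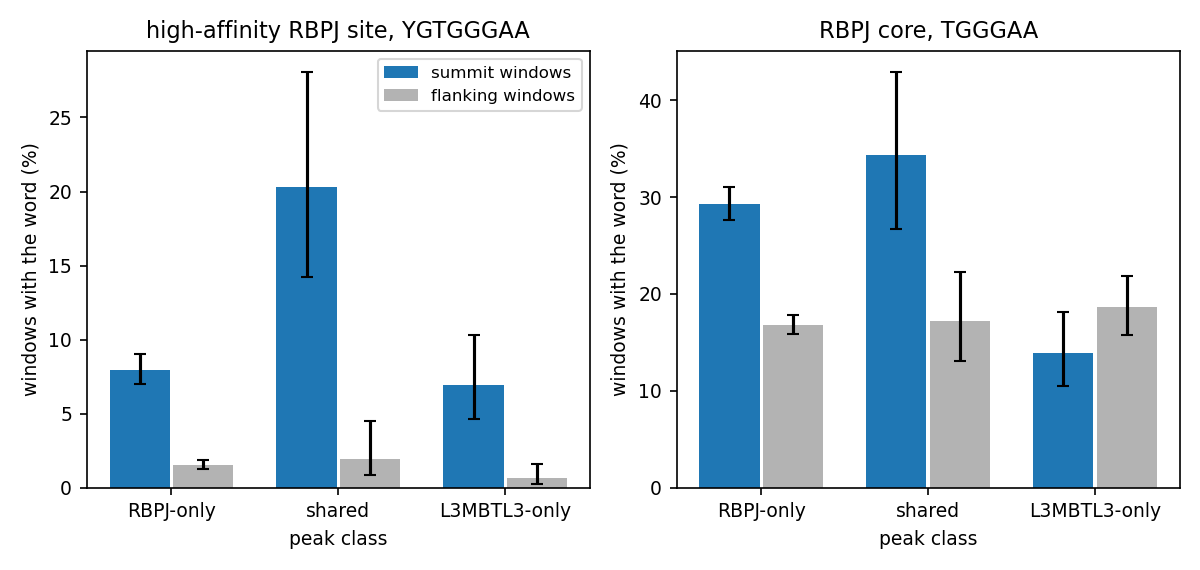
Percent of windows (y axis) with the high-affinity RBPJ word (left) and the core word (right) in 3 peak classes (x axis), at summits (blue) and in flanking windows 2 kb away (grey). Shared windows are centred on the RBPJ summit. Bars start at 0 and error bars are 95% Wilson intervals. The high-affinity word is in 20.3% of shared summit windows, against 7.97% and 6.94% in the other classes.

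Words of AP-1, TEAD and E-box factors were less frequent in shared than in RBPJ-only peaks. The AP-1 word was in 11.6% of RBPJ-only and 3.13% of shared windows (adjusted p = 0.00695), the TEAD word in 14.2% and 3.91% (adjusted p = 0.00181), and the E-box in 7.11% and 1.56% (adjusted p = 0.0450; Fisher's exact tests). Promoter position differed along with these classes (82.8% of shared and 63.3% of RBPJ-only peaks), and RBPJ peaks at promoters held AP-1 in 3.78% and TEAD in 7.46% of cases, against 24.5% and 24.9% away from them. For the E-box these shares were 7.73% and 5.33%. The classes were not compared within promoters. L3MBTL3-only windows held AP-1 in 2.21% and TEAD in 2.84% of cases, below RBPJ-only windows (odds ratios of 5.80 and 5.64 for RBPJ-only over L3MBTL3-only, Fisher's exact, adjusted p = 5.79e-08 and 4.02e-09). The 13 words were tested in 5 peak classes: all RBPJ, all L3MBTL3, shared, RBPJ-only and L3MBTL3-only peaks. These classes overlap, so an enrichment can count more than once. Of the 65 pairs of word and class, 28 were found more often at summits than in flanks and 4 less often (Fisher's exact, adjusted p under 0.05). Against TSS windows of the same CpG class, 19 were found more often and 2 less often. ETS and YY1, both above flanks in RBPJ peaks (odds ratios 19.1 and 15.1), did not pass against those TSS windows (0.649% against 0.684%, and 0.513% against 0.561%, Fisher's exact, adjusted p = 1.00 each).

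Notch target genes lay near peaks of both proteins more often than other protein-coding genes. A summit of RBPJ lay within 10 kb of a TSS for 11.3% of 19748 genes, of L3MBTL3 for 1.58%, and of a shared RBPJ peak for 0.603%. This background, used for all lists, was not matched on CpG class or gene activity. Promoter peaks were at CpG-rich TSS in 94.5% (RBPJ) and 99.5% (L3MBTL3) of cases, against 56.4% of all TSS. How far the odds ratios of the lists reflect CpG class or gene activity was not tested. Of 26 Notch targets, 11 had an RBPJ peak (odds ratio 5.75, 2.64 to 12.5, Fisher's exact, adjusted p = 1.67e-04), 6 an L3MBTL3 peak (19.0, 7.57 to 47.6, adjusted p = 3.73e-05) and 3 a shared peak (22.05, 6.53 to 74.4, adjusted p = 0.00702). At a -log10 q of at least 5, asked for shared peaks of the RBPJ peak only, these odds ratios were 16.5, 55.01 and 46.6, and at 50 kb that of L3MBTL3 was 10.2. With that q asked of both peaks, a test chosen after the data were seen, 24 shared RBPJ peaks were left, near 2 Notch targets, HES4 and HEY2 (odds ratio 82.1, 18.2 to 371, Fisher's exact, adjusted p = 0.00530). HES4, HEY2 and NOTCH1 had the shared peaks. HES1 had 4 RBPJ peaks (folds 6.80 to 8.82) and no L3MBTL3 peak within 10 kb. CCND1, CDKN1A, HES7, ID3, JAG1, LFNG and MYC also had RBPJ peaks, with folds of 3.21 to 6.29. HEY1, NRARP (fold 6.98, UTR, with 1 high-affinity site) and HES5 had L3MBTL3 peaks without an RBPJ peak within 10 kb, and the HES5 peak lay closer to a TSS of PANK4 (466 bp) than to HES5 (3201 bp). Within 50 kb HEY1, NRARP and HES5 each had an RBPJ peak, and NRARP had the shared peak upstream of it.

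Of 37 Notch pathway components, 12 had an RBPJ peak (odds ratio 3.76, 1.89 to 7.50, Fisher's exact, adjusted p = 0.00126), and 2, NOTCH1 and RBPJ, had L3MBTL3 and shared peaks (adjusted p = 0.325 and 0.0975). The shared result passed with a -log10 q of at least 5 for the RBPJ peak (Fisher's exact, adjusted p = 0.0370) but not for both peaks, where the gene RBPJ was the 1 member left (0.283). Other members with RBPJ peaks included NOTCH2, JAG1, LFNG, ADAM17, FBXW7, MAML1, MAML3, POFUT1 and PSENEN, and the stronger NOTCH2 peak (fold 6.06) lay in repeated sequence. The peaks of ADAM17 (fold 3.35, -log10 q 1.44) and LFNG (3.62 and 1.56) were weak. At a -log10 q of at least 5, 6 members kept an RBPJ peak: NOTCH1, NOTCH2, RBPJ, FBXW7, MAML1 and MAML3. The PSENEN peak lay in IGFLR1, 4884 bp from the PSENEN TSS. NOTCH1, JAG1 and LFNG are in both Notch lists.

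Of 34 members of the list of RBPJ corepressors and demethylase complexes, 13 had an RBPJ peak (odds ratio 4.86, 2.43 to 9.72, adjusted p = 1.62e-04), 6 an L3MBTL3 peak (13.5, 5.57 to 33.0, adjusted p = 9.79e-05) and 3 a shared peak (16.3, 4.93 to 54.2, adjusted p = 0.00780; Fisher's exact tests). The shared ones were KDM1B, which encodes a histone demethylase (RBPJ fold 7.82, L3MBTL3 fold 5.96), SPEN, which encodes an RBPJ corepressor (3.35 and 8.20), and KMT2D, whose peak lies in an RHEBL1 intron, 8815 bp from the KMT2D TSS and 228 bp from that of RHEBL1. KMT2D encodes a histone methyltransferase rather than a corepressor. The list also holds the acetyltransferase genes EP300, KAT2A and KAT2B, none with a peak within 10 kb, and was not tested without these genes. CTBP1, PHF21A and SHARPIN had L3MBTL3 peaks outside shared regions, and the SHARPIN peak was 415 bp from CYC1. SHARPIN was listed by its symbol and is not the corepressor SHARP, which SPEN encodes. Without it 12 of 33 members had an RBPJ peak (odds ratio 4.48, 2.20 to 9.12, Fisher's exact, adjusted p = 4.45e-04) and 5 an L3MBTL3 peak (11.3, 4.32 to 29.3, adjusted p = 0.00112). Other members with RBPJ peaks included NCOR1 (8.01), RCOR1 (8.59), RCOR3, SIRT1, TLE1, RITA1, L3MBTL1, PHF21A and SHARPIN (237 bp from CYC1). With a distance of 1 kb the call for this list ended for L3MBTL3 (Fisher's exact, adjusted p = 0.0538) and for shared peaks (0.565), and it ended with a -log10 q of at least 5 (0.726, and 0.333 with the q of the RBPJ peak only). With that q for both peaks of a shared pair 0 members were left.

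RBPJ peaks were also near 17 of 25 AP-1 and immediate early genes (odds ratio 16.7, 7.21 to 38.8, Fisher's exact, adjusted p = 2.50e-10), among them IER3 (fold 8.19, the shared peak nearest to FLOT1), KLF4 (7.73) and KLF10 (6.81). They were near 10 of 19 YAP/TEAD targets (8.71, 3.54 to 21.5, Fisher's exact, adjusted p = 5.67e-05), among them FJX1 (6.61), AXL (6.53) and AJUBA (6.27). They were near 6 of 19 p53 targets (3.61, 1.37 to 9.51, Fisher's exact, adjusted p = 0.0273), among them GDF15 (8.18), and near 15 of 66 replication-dependent histone genes (2.31, 1.29 to 4.11, adjusted p = 0.0190). The p53 call ended at 50 kb (exact tests, adjusted p = 0.352), and the histone call ended at 1 kb (0.713) and within chromosomes (0.560). Clustered histone genes share peaks, so they are not independent and the histone p may be too small. The RBPJ peak at 27799331 to 27799396 on chromosome 6, for example, counted for H2AC15, H2BC15, H4C11 and H4C12. No RBPJ peak was within 10 kb of 39 HOX genes (Fisher's exact, adjusted p = 0.0297) or 381 olfactory receptor genes (1.61e-19). The HOX call ended at 1 kb (0.0793) and at the stricter q (0.798). HOX and olfactory receptor genes also lie in clusters, so their p values may be too small as well. Ribosomal protein genes (16 of 84, Fisher's exact, adjusted p = 0.0510, and 0.0252 at 50 kb), NF-kB targets (4 of 20, 0.321), cell cycle genes (5 of 24, 0.234), mesenchymal genes (3 of 24, 0.749) and luminal epithelial genes (1 of 22, 0.543) did not pass. L3MBTL3 peaks were near 2 of the 25 AP-1 and immediate early genes (Fisher's exact, adjusted p = 0.207), 1 of the 24 cell cycle genes (0.743) and 0 members of the other 9 lists. Of those 9, olfactory receptors passed as depleted (Fisher's exact, adjusted p = 0.0249; 1.00 for each of the other 8), and lost the call at 1 kb (0.0538), at the stricter q (1.00) and within chromosomes (0.105). Shared peaks were near 1 AP-1 and immediate early gene, IER3, and 1 cell cycle gene, CCNE2 (Fisher's exact, adjusted p = 0.393 each), and near 0 members of the same 9 lists (0.416 for olfactory receptors and 1.00 for each of the other 8).

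**Figure D4:**
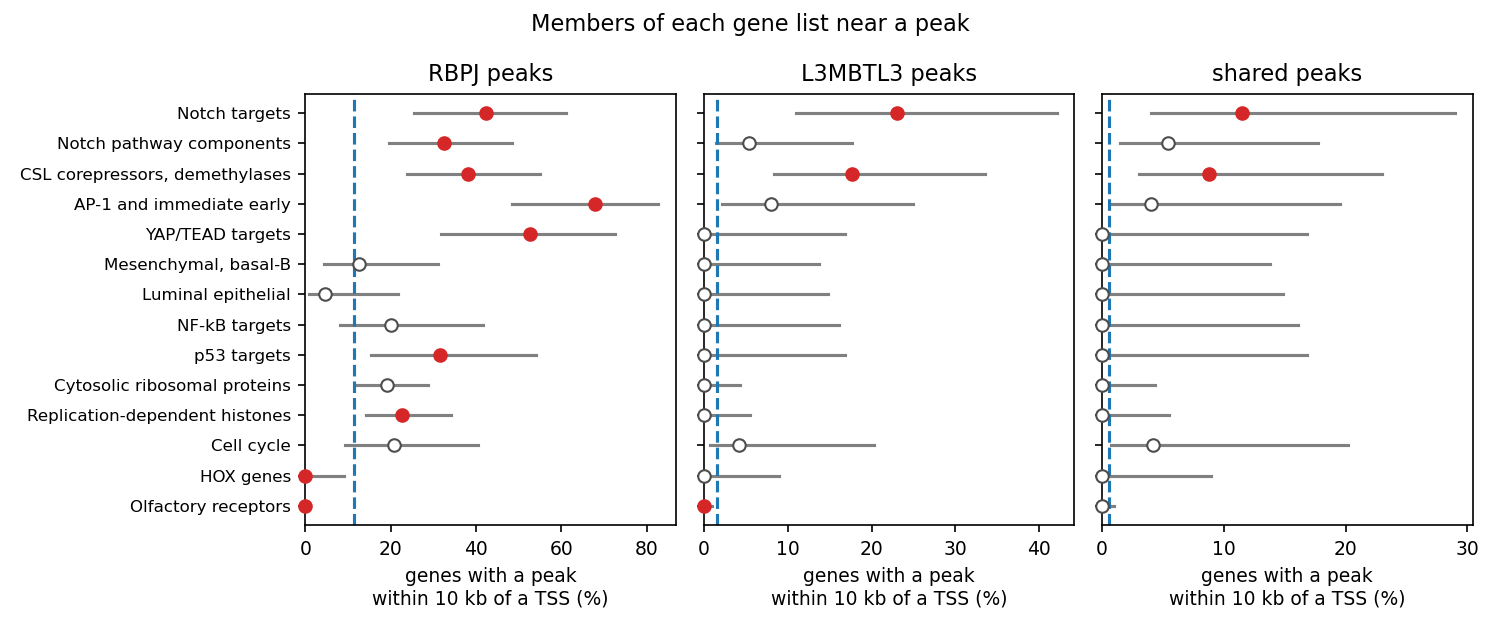
Percent of each gene list's members with a peak within 10 kb of a TSS (x axes, which differ between panels) for RBPJ, L3MBTL3 and shared peaks, with lists on the y axis. Points are percents with 95% Wilson intervals, filled red where the adjusted p of Fisher's exact test is under 0.05, and the dashed line is the percent over all protein-coding genes. Notch targets stand at 42.3%, 23.1% and 11.5%.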

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

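Merged regions, same-chromosome TSS, removal of repeated sequence, CpG-class motif controls, comparisons within chromosomes and the corepressor list without SHARPIN were chosen after seeing the data. No paired analysis was possible because each antibody had 1 library, which also left no replicate to omit, and unknown read counts limit every fold. The overlap stayed above the highest of 1000 random placements under every placement, threshold and overlap rule run. Where values moved, the cause was not tested beyond what each rule changes by construction.

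The share of L3MBTL3 peaks overlapping RBPJ was 22.3% at a -log10 q of at least 5, 24.1% with 50% of the shorter peak covered, 22.7% with summits within 100 bp, 49.3% within 1 kb and 36.9% of merged regions. Leaving out each chromosome gave 25.6 to 29.9%. The lowest was without chromosome 6, which held 29 of the 128 shared RBPJ peaks and the most RBPJ peaks per gene. The fold over random placement (814 as reported, over a mean near 0) was 1533 at the stricter q, 1476 with folds of at least the list median, 964 with 50% covered, 205 within 1 kb and 91.0 with local placement. Against promoter placement (19.2) it was 50.9 at the stricter q, 11.1 with TSS of the same CpG class and 16.3 with TSS on the same chromosome.

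The chance that a shared peak was stronger was 54.1% for RBPJ peaks away from promoters and 66.4% for L3MBTL3 by -log10 q. The share at promoters was 60.3% (RBPJ) and 73.2% (L3MBTL3) within 500 bp, 71.1% and 86.5% within 5 kb, and for RBPJ 56.1% at the stricter q.

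The core word in all L3MBTL3 peaks (odds ratio 1.14) passed over whole peaks (1.65), with controls 10 kb away (1.44), with controls of the same CpG class (1.42) and at the stricter q (1.87). In L3MBTL3-only peaks (0.705) its odds ratio turned to 1.10 over whole peaks, 1.03 with controls 10 kb away and 1.59 at the stricter q, none past the threshold. The high-affinity word passed in all 5 overlapping classes under all 6 alternatives, with odds ratios that moved. For L3MBTL3-only peaks (11.7) they were 3.21 with random TSS, 5.18 with controls 10 kb away, 5.30 with the same CpG class, 6.85 in windows of 50 bp, 20.1 over whole peaks and 45 at the stricter q (2.57 to 789), where 0 of 112 controls held the word and 0.5 was added to each count. For shared peaks (12.8) they were 20.1 with random TSS, 32.4 with controls 10 kb away and 44.4 in windows of 50 bp. Of other words, 4 pairs were found less often than in flanks, and 2 with random TSS, 2 with CpG-class TSS and 2 in windows of 50 bp.

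Lists near L3MBTL3 peaks above background fell from 2 to 1 at 1 kb and 1 at the stricter q, and those near shared peaks from 2 to 1 at 1 kb and 1 with the stricter q in both lists (the stricter q alone being that of the RBPJ peak for shared peaks). Lists below background fell for RBPJ from 2 to 1 at 1 kb and 1 at the stricter q, and for L3MBTL3 from 1 to 0 at 1 kb, 0 at the stricter q and 0 within chromosomes. Notch targets passed for RBPJ and L3MBTL3 under all 4 alternatives and for shared peaks under all 5, with odds ratios of 4.56 to 16.5 for RBPJ, 10.2 to 55.01 for L3MBTL3 and 18.1 to 82.1 for shared peaks (46.6 at the stricter q of the RBPJ peak, 82.1 with it in both lists, with 2 targets left). Among lists other than Notch targets, 13 calls were lost, 0 of them by leaving out SHARPIN, 2 were gained and 10 uncalled odds ratios changed side: mesenchymal genes for RBPJ at 50 kb (0.718), luminal genes for L3MBTL3 at 50 kb (1.60), and 8 that fell to 0 with 0 members left. These were NF-kB and cell cycle for RBPJ, AP-1 and cell cycle for L3MBTL3 and cell cycle for shared peaks at the stricter q (each 0), AP-1 for shared peaks at 1 kb (0), and AP-1 and cell cycle for shared peaks with that q in both lists (each 0). The corepressor list, called for shared peaks, also fell to 0 with that q in both lists.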

Other observations

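The comparison of promoter and other peaks by motif, the counts per chromosome and the tests of open promoters, gene density, read depth and CpG class were chosen after the data were seen. The placement, repeat and 1 kb tests were set before their results were seen, with the count of 127 shared peaks and the motif shares already known.

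RBPJ peaks away from promoters differed in sequence from those at promoters. Of 1050 such peaks, 24.5% (21.97 to 27.2) held an AP-1 word, 24.9% (22.3 to 27.6) a TEAD word, 6.48% (5.14 to 8.13) a RUNX word and 13.7% (11.8 to 15.9) the high-affinity RBPJ word. Of 1876 promoter peaks, 3.78%, 7.46%, 1.65% and 5.60% did (odds ratios 8.24, 4.10, 4.12 and 2.68, Fisher's exact, adjusted p = 2.56e-61, 1.30e-36, 1.38e-10 and 1.08e-12). Promoter peaks more often held the GC box (29.0% against 8.86%) and the NFY word (8.37% against 2.95%; Fisher's exact, adjusted p = 1.94e-39 and 9.36e-09). For 77 L3MBTL3 peaks away from promoters, AP-1 was in 5.19% (2.04 to 12.6), against 1.36% of 367 promoter peaks (Fisher's exact, adjusted p = 0.122). The NRF1 word was in 4 of the 77 (5.19%) and 1 of the 367 (0.272%). Its odds ratio of 20.1 (2.21 to 182, Fisher's exact, adjusted p = 0.0122) thus rests on few peaks. L3MBTL3 peaks were more than the share of protein-coding genes gives on chromosomes 6 (57 against 23.1) and 10 (36 against 16.4), and fewer on 11 (4 against 29.0), 12 (8 against 22.9), 19 (14 against 32.3) and X (7 against 19.4; exact binomial tests, adjusted p of 0.00867 or less over 23 chromosomes).

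For the overlap of the RBPJ and L3MBTL3 lists, a shared preference for promoters, for CpG-rich promoters or for the same 100 kb segments gave at most 16, 24 and 5 shared peaks in 1000 placements against 127 observed, and without repeated sequence at most 15 against 120, so none of these alone accounts for the count. Gene activity was not matched in these placements, so a shared preference for active promoters was not tested. The high-affinity RBPJ site was in 20.3% of shared peaks (14.3 to 28.1) and in at most 17.2% (mean 9.80%) of 1000 draws of RBPJ-only peaks matched on fold and promoter position. Shared peaks thus held it more often than RBPJ-only peaks of like fold and position, a difference largely known before the draws. The draws were not matched on openness or CpG class, and the interval includes the highest draw. They therefore cannot decide whether pull-down of open promoters whatever the antibody caused the shared peaks. For the 84 of 128 shared RBPJ peaks without the core word, such pull-down cannot be told apart from joint binding, since no other antibody was analysed here. A control library common to both peak calls was not tested. Joint binding of both proteins at Notch target and other promoters is therefore a hypothesis that may hold for part of the shared peaks.

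RBPJ peaks per 100 protein-coding genes ranged from 2.02 (1.04 to 3.53) on chromosome 15 to 31.8 (28.5 to 35.5) on chromosome 6, with exact Poisson intervals, a 15.7-fold difference that gene density does not explain. A candidate explanation is local read depth or DNA copy number: at a -log10 p of 7 to 9, the only range tried, the median fold fell with peaks per gene over 22 chromosomes (Spearman rho -0.673, permutation p = 9.30e-04, adjusted p = 0.00186; Pearson r -0.835, p = 1.00e-05, the smallest that permutations can give, adjusted p = 2.00e-05; rho -0.569 and r -0.730 without chromosomes 6 and 22). Chromosome 15 had too few such peaks, the test was found after looking at these counts, and attempts to recover the background itself from fold and p gave no single solution. Whether such an effect acted alike on both libraries stays open. Peaks per gene of the 2 lists correlated over 23 chromosomes (Spearman rho 0.456, permutation p = 0.0302, adjusted p = 0.0302; Pearson r 0.561, p = 0.00556, adjusted p = 0.00556), falling to rho 0.303 and r 0.364 without chromosomes 6 and 20, on which it partly rests, and no biological explanation was tested.

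The high-affinity RBPJ word was in 6.94% of 317 L3MBTL3-only peaks, against at most 4.10% (mean 1.43%) in 1000 draws matched on TSS distance and CpG class. This argues against TSS distance and CpG class of the TSS as the cause. Differences in CpG content within a class were not matched. Among the 225 that lay over 1 kb from any RBPJ peak it was in 7.56%, against at most 4.44%, which argues against RBPJ peaks of the same promoters as the cause. A hypothesis is that some of these are RBPJ-bound promoters, such as HEY1, that the RBPJ list misses. Whether RBPJ reads are there was not tested, since only called peaks were analysed.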
